A study of Rattus norvegicus with 6 samples.

How the data were processed

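Hippocampal RNA of 6 male Wistar rats, kept under 12 h of light and 12 h of dark, was analysed, 3 orchidectomized and 3 sham-operated. Per the labels' protocols, 200 ng of total RNA per animal was amplified and labelled with Cy3. Groups and replicate numbers were taken from the labels, which call the samples biological replicates.

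Per the file headers, each array was scanned in 1 channel and read with Agilent Feature Extraction 10.5.1.1, whose processed signal is a background-subtracted and spatially detrended intensity. Saturation, outlier and above-background flags were used as the scanner software set them, per the file headers. The authors' deposited value table holds log2 values that equal the log2 processed signal of each probe plus 1 constant per array. The differences from log2 processed signal, taken as a median per array, ran from -0.32 to 0.72, and the column medians were 8.02, 7.94 and 7.91 for orchidectomized 1 to 3 and 7.77, 7.62 and 8.05 for sham 1 to 3. The scale is log2 and 1-colour values have no direction, while the centring, the origin of the constants, stays unknown. The genome build named in the file headers differs from that of the reference, so no coordinates are given.

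Of 44254 spots per array, 1377 control spots were left out, as were spots with a non-uniformity or population outlier flag. The remaining spots held 30367 probes, 28977 spotted once and 1390 spotted 10 times. Log2 values of a probe's spots were averaged after log2(gProcessedSignal) was taken, and each array's 75th percentile over probes was subtracted. A probe counted as well above background or saturated when at least 50% of its spots did. RefSeq accessions on the array were matched without versions to the gene table of the GRCr8 assembly, which named 18004 probes and left 12363 without a symbol.

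Probes well above background on all 3 arrays of at least 1 group were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment. This left 24631 probes, 15057 of them named, and 12632 genes. In total 43 gene lists, each with at least 5 tested genes, were tested with camera at the preset inter-gene correlation of 0.01, with the brightest probe per gene, and again with an estimated correlation. The lists cover hormone response, brain functions, immunity, cell types, hippocampal fields, neighbouring tissues and gene families. The test, the lists, the rule for named genes and the main alternatives were chosen before the data were examined.

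Named genes were the 12 per direction with the largest change among named probes with an adjusted p under 0.05 and groups that did not overlap, filled from probes with an unadjusted p under 0.01. To these came up to 4 members per described list with the smallest unadjusted p, and Esr1, Esr2, Nr3c1, Nr3c2, Srd5a1, Cyp19a1 and Ttr; 1 further gene of the rule is not reported here. Genes given for the array labelled sham 2 were taken from the members of each list that differed most on that array, after their values were seen. Where a probe was not well above background on any array of a group, "at least" folds set the bright group's mean against the dim group's mean of the higher of the probe's value and the lowest value among probes well above background on that array. The same was done for the array labelled sham 2 alone, where a saturated value was also taken as a lower bound.

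The arrays lay on 4 slides and were scanned on 2 days. Slide 1 held orchidectomized 1 and 2, slide 2 orchidectomized 3 and sham 1, and slides 3 and 4 held the array labelled sham 2 and sham 3. Scan day 1 held the 3 orchidectomized arrays and sham 1, and day 2 held the array labelled sham 2 and sham 3. Alternatives were normexp with an offset of 50, quantile and median scaling, other brightness filters, the authors' deposited values, other variance models, array weights, blocks for replicate number, slide and scan day, a choroid plexus covariate, and leaving out each array. Normexp had been planned on mean spot signals, and median spot signals were used in their place. Median scaling moved the median difference of all tested probes to -0.101 over 6 arrays. Normexp gave 0.069 over 6 arrays and 0.077 without the array labelled sham 2. The changes under these settings are relative to those medians. The comparison without the array labelled sham 2 under each other setting was added after the data were seen.

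The fits were tested on simulated data with 100 probes changed at each of 2 sizes. Changes of 1 log2 unit were recovered in 0 of 100 probes at the spread of the 6 arrays and in 33 of 100 without the array labelled sham 2, and 5 unchanged probes were called in the latter. A list shifted by 1 log2 unit was recovered at both spreads. The simulated values were independent between probes and did not keep the profile of the array labelled sham 2. Their spread was the one limma had already drawn toward a common value, and all changed probes were changed at once. Both can make recovery easier than in the measured data.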

Results

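Gene expression was measured in the hippocampus of male Wistar rats that had been orchidectomized (both testes removed) or sham-operated at 2 months of age and killed 2 weeks after surgery. Each group held 3 biological replicates, and each RNA sample was hybridised to its own array, 6 arrays in all. The arrays were 1-colour Agilent rat arrays read in the Cy3 channel. Between 23788 and 26176 of 30367 probes were well above background on each array, and the number of arrays limits the precision of every comparison. Values are log2 intensities relative to the 75th percentile of the array, and differences are orchidectomized minus sham.

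The comparison asked which hippocampal genes differ between orchidectomized and sham-operated males. The array labelled sham 2 carried an expression profile unlike that of the other 5 arrays. Genes typical of the choroid plexus, the secretory epithelium that makes cerebrospinal fluid, were a median of 7.70 log2 units higher on it (SD over 31 genes 2.64), and genes of glutamatergic neurons had a median of -6.60 (SD over 16 genes 2.28). The mineralocorticoid receptor gene Nr3c2 differed by -0.06 with a standard error of 0.13 between 3 orchidectomized and 2 sham arrays once that array was left out. Among single transcripts, an unnamed transcript (NM_001037357) was well above background on all 3 sham arrays and on 0 of the 3 orchidectomized arrays, at least 5.31-fold brighter in the former, and did not pass the adjusted threshold.

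Over all 6 arrays, limma called 0 of 24631 tested probes at a Benjamini-Hochberg adjusted p under 0.05. The smallest adjusted p was 0.185, and 180 probes (22 higher, 158 lower) had an unadjusted p under 0.05 where 1232 would be given by chance. The count was 13 with array weights, which gave the array labelled sham 2 a weight of 0.028, and 1 each with quantile normalization and with the choroid plexus list mean as a covariate. The values of the groups did not overlap at 8% of the tested probes, and chance gives 10% for 3 arrays against 3. Without the array labelled sham 2, 0 of 25208 probes were called, and the smallest adjusted p was 0.0603. An unadjusted p under 0.05 was found for 682 probes (113 higher, 569 lower) where chance gives 1260. The filter then admitted probes bright on both remaining sham arrays alone, which favours lower values. The groups did not overlap at 16.3% of the tested probes, and chance gives 20% for 3 against 2. In that comparison the count was 18 (1 higher) with the authors' deposited values, 10 with scan day as a block and 2 with quantile normalization. It was above 0 when sham 1 or sham 3 was left out as well, with most of the called probes lower. A lone sham array was then assumed to vary like the others, and probes bright on that array alone were tested. Such counts are therefore not given as differences between the groups. Simulated changes of 2 log2 units were recovered in 0 of 100 probes at the spread of the 6 arrays and in 91 of 100 at the spread without the array labelled sham 2. The latter share does not carry over to the measured values. Without that array the olfactory receptor gene Olr655 differed by -4.47 and was not called (limma adjusted p 0.122). The hair keratin gene Krt35 differed by -3.42 and was not called either (limma adjusted p 0.131).

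On the array labelled sham 2, the 31 choroid plexus genes detected on any array lay a median of 7.70 log2 units above the median of the other 5 arrays (SD over genes 2.64), and 30 of them were higher by over 1 log2 unit. The tight junction gene Cldn2 had a log2 value of 4.77 there and between -7.73 and -5.52 on the others. Kl, which encodes klotho, had 3.72 there against -7.87 to -5.65, and the channel gene Kcnj13 was saturated there and at least 830-fold brighter than the mean of the others. Ependymal genes, which include those of motile cilia, were a median of 4.25 higher (19 genes), with the cilia regulator Foxj1 at 3.79 against -2.73 to -1.54. Antigen presentation genes were a median of 2.53 higher (22 genes), and Cd74, the invariant chain, had 2.34 against -3.31 to -1.24. Genes of meninges and fibroblasts were a median of 1.75 higher (30 genes).

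The same array was low in hippocampal transcripts. The 16 glutamatergic neuron genes had a median difference of -6.60 log2 units from the median of the other 5 there (SD over genes 2.28), and all 16 were lower by over 1 log2 unit. Neurod6 had -6.81 there and 2.18 to 2.78 on the other 5, and the dentate gyrus neuropeptide gene Pdyn had -6.59 against 1.33 to 2.03. Slc17a7, the vesicular glutamate transporter 1 gene, was not well above background there and was at least 84.8-fold brighter on the others. Medians were -5.16 for GABAergic interneuron genes, -4.24 for astrocyte genes and -4.25 for myelin genes. Microglial genes had a median of -0.80, with P2ry12 at -2.21 against 0.13 to 0.82. The array correlated across probes with the others at 0.803 to 0.813, while the other 5 correlated with each other at 0.987 to 0.996; probes are not independent replicates. All 9 scanner quality measures were in range on every array, including this one.

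**Figure D1:**
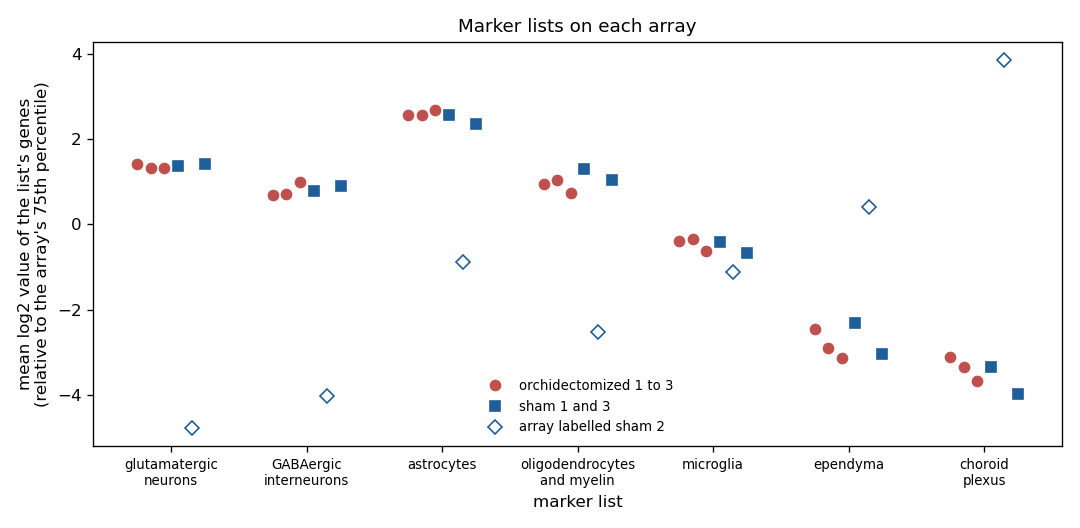
Mean log2 value of the detected genes of 7 marker lists (horizontal axis) on each of the 6 arrays, relative to the array's 75th percentile (vertical axis); each point is 1 array and the open diamond is the array labelled sham 2. That array has a choroid plexus mean of 3.84 where the other 5 lie between -3.98 and -3.10, and a glutamatergic neuron mean of -4.77 where the others lie between 1.32 and 1.41.

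In the full comparison 25 of 43 gene lists were called with limma's camera at the preset correlation, 19 higher in the orchidectomized group and 6 lower, and 0 were called with an estimated correlation (smallest adjusted p = 0.683 with an estimated correlation). The glutamatergic neuron list had a median difference of 2.34 (16 of 16 genes higher, adjusted p 5.65e-05; adjusted p = 0.683 with an estimated correlation). The choroid plexus list had -2.35 (27 of 28 genes lower, adjusted p 0.000223; adjusted p = 0.701 with an estimated correlation). Glutamate receptor genes had 2.22 (28 of 28 higher, adjusted p 2.70e-07), synaptic plasticity genes 1.65 (35 of 37, adjusted p 2.70e-07), astrocyte genes 1.46 (18 of 20, adjusted p 1.22e-05) and myelin genes 1.02 (23 of 23, adjusted p 0.000368), and ependymal genes had -1.48 (18 of 19 lower, adjusted p 0.00148). With an estimated correlation the adjusted p of these lists was 0.683, and 0.694 for myelin. In these lists 0 genes were called over all genes tested and 0 adjusted over the list alone. The glutamatergic median was -0.09 and the choroid plexus median 0.21 without the array labelled sham 2, so the sign of both turned with that array. With slide and with scan day as a block the glutamatergic median was -0.09 and 0.03, and the choroid plexus median -0.18 and -0.04. The count of lists was 10 with array weights, 7 with slide as a block, which compares orchidectomized 3 with sham 1 alone, and 9 with scan day as a block, which compares the 3 orchidectomized arrays with sham 1 alone. Both blocks thus leave the array labelled sham 2 without weight in the difference. Of the 25 lists, 7 were also called without the array labelled sham 2, and 4 of these in the same direction.

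The steroid hormone genes named here did not differ past the threshold. Nr3c2, the mineralocorticoid receptor gene, had a mean of 2.03 ± 0.09 (SD, n = 3) in orchidectomized and 2.09 ± 0.01 (SD, n = 2) in sham arrays without the array labelled sham 2, a difference of -0.06 with a standard error of 0.13 (limma adjusted p 0.988). The corresponding differences were -0.12 for Esr2, the estrogen receptor beta gene, -0.05 for Nr3c1, the glucocorticoid receptor gene, and -0.11 for Srd5a1, which encodes a steroid 5-alpha-reductase. The log2 value of Nr3c2 on the array labelled sham 2 was -0.24, and with that array included the difference of Nr3c2 was 0.72 with a standard error of 0.68 (limma adjusted p 0.775). Esr1 had no probe that passed the brightness filter, and no probe was named Cyp19a1 here. The androgen response list had a median of -0.08 without the array labelled sham 2, with 15 of 34 genes higher and 19 lower (limma camera adjusted p 0.956).

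NM_001037357 showed the smallest adjusted p in both comparisons. The probe with the smaller p had -9.83 ± 0.18 (SD, n = 3) in orchidectomized and -5.37 ± 0.46 (SD, n = 3) in sham arrays, and was at least 5.31-fold brighter in the sham arrays (limma adjusted p 0.185). The second probe of the transcript lay in the same direction and was at least 1.97-fold brighter in the sham arrays (limma adjusted p 0.775). On the slide that held orchidectomized 3 and sham 1 the measured values of the probe with the smaller p differed by -4.88, and with scan day as a block by -4.98. Both values rest on sham 1 alone and on orchidectomized values not well above background, so their size is not exact. The transcript was singled out after its values were seen, since it carries no gene symbol here.

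None of the genes that the naming rule gave passed the adjusted threshold. Over 6 arrays it gave 1 gene with a higher and 8 with a lower value, and Gfral, the receptor gene for the hormone GDF15, was the higher one. Gfral was well above background on all 3 orchidectomized arrays and on 0 of 3 sham arrays, at least 3.11-fold brighter (limma adjusted p 0.775). The 8 genes with lower values were Or1n1b, Pla2g2a, Adad1, Pde6h, Lrrc71, Or1e27, Wnt2b and Rln1. Pla2g2a, a secreted phospholipase A2, was at least 2.95-fold brighter in the sham arrays, and Pde6h, a cone phosphodiesterase subunit, differed by -1.45. Wnt2b, which encodes a Wnt ligand, differed by -0.85. The relaxin gene Rln1 differed by -0.68 and had means of -5.46 ± 0.02 (SD, n = 3) in orchidectomized and -4.78 ± 0.03 (SD, n = 3) in sham arrays. The sham values of all 9 genes include the array labelled sham 2 with its choroid plexus profile. Rln1 had -4.79 on that array and -4.80 and -4.75 on sham 1 and sham 3. Gfral had -9.49 there and -8.11 and -8.58 on the other sham arrays. With normexp background correction 0 of these 9 genes kept an unadjusted p under 0.01, and Lrrc71 and Or1e27 turned to 0.09 and 0.11. The median of all tested probes was 0.069 under normexp, so these 2 values lie near no change relative to all probes.

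The rule gave 12 genes in each direction without the array labelled sham 2, none past the adjusted threshold. Ttr, which encodes the thyroid hormone carrier transthyretin, had 4.81 ± 0.42 (SD, n = 3) in orchidectomized and 3.23 ± 0.34 (SD, n = 2) in sham arrays. The measured difference was 2.99-fold (limma adjusted p 0.988), a lower bound because the probe was saturated on orchidectomized 1. On the shared slide Ttr differed by 0.89, and on the first scan day by 1.34. Both are against sham 1 alone, with a sign that the rule of groups without overlap had fixed. The matrix protein gene Ccn1 differed by 1.15, the membrane metalloproteinase gene Mmp14 by 0.83 and the cystine transporter gene Slc7a11 by 0.99. Their values on the array labelled sham 2 were -0.66, 3.74 and -8.17, against orchidectomized means of -1.61, -0.37 and -2.14. Ccn1 and Mmp14 were thus higher on that array and Slc7a11 was lower. The other genes with higher values were Gfral, Or5g9, Ccdc167, Vom2r67, Vom2r69, Lpgat1, Dmtf1 and Pbld1, and 1 of the 3 other probes of Dmtf1 had the opposite sign. Among the genes with lower values, the olfactory receptor gene Olr655 was at least 4.79-fold brighter in sham arrays (limma adjusted p 0.122) and the hair keratin gene Krt35 at least 3.11-fold (limma adjusted p 0.131), both on 2 of 2 sham arrays and 0 of 3 orchidectomized arrays. Both genes passed the brightness filter through the sham arrays alone, so this pattern follows in part from how they were picked. On the array labelled sham 2 the values of Olr655 and Krt35 were -8.69 and -9.62. The other 10 were Or4c125, Cst12, Pcgf6l1, Pkp3, Or4c107, Dspp, Or1n1b, Tnk1, Olr1493 and Acsm1, of which Or4c107, Or1n1b and Olr1493 turned to 0.09, 0.01 and 0.08 with normexp. The median of all tested probes was 0.077 in that setting, so relative to all probes these turns are near no change. Against sham 1 alone, Ccn1, Mmp14 and Slc7a11 differed by 0.48, 0.56 and 1.02 on the shared slide and by 0.75, 0.54 and 0.90 on the first scan day, with signs that the rule of groups without overlap had fixed. With the authors' deposited values Olr655, Krt35, Pcgf6l1, Or4c107, Dspp, Acsm1 and Gfral passed the adjusted threshold.

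**Figure D2:**
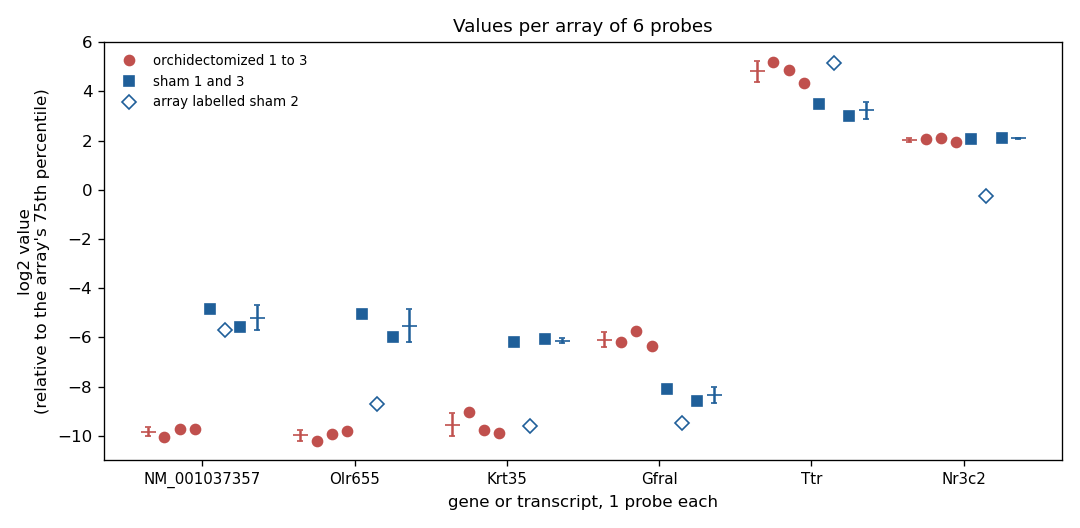
Log2 values relative to the array's 75th percentile (vertical axis) of 6 probes (horizontal axis) on each array; points are arrays, the open diamond is the array labelled sham 2, and dashes with bars are the mean and SD of the 3 orchidectomized arrays and of sham 1 and sham 3. NM_001037357 lies between -10.04 and -9.72 in the orchidectomized arrays and between -5.70 and -4.85 in all 3 sham arrays, and Nr3c2 on the array labelled sham 2 lies at -0.24.

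Without the array labelled sham 2, 13 of 43 lists were called with the preset correlation, 7 higher and 6 lower, and 0 with an estimated correlation. The count was 7 with quantile normalization and 8 with the choroid plexus list mean as a covariate, and 8 when orchidectomized 2 was left out as well. Ribosomal protein genes had a median difference of 0.25, with 72 of 77 genes higher (adjusted p 3.17e-12; adjusted p = 0.824 with an estimated correlation). Their median was 0.33 on the shared slide, 0.08 on the first scan day, where sham 1 is the lone sham array, 0.45 against sham 3 and 0.11 without orchidectomized 3. The list's mean log2 value was 4.35 on orchidectomized 3 and 4.01 and 3.89 on orchidectomized 1 and 2, with 4.07 on sham 1 and 3.64 on sham 3. Genes of oxidative phosphorylation had 0.09, with 34 of 41 higher (adjusted p 6.81e-05; adjusted p = 0.824 with an estimated correlation), and 0.23 on the shared slide, 0.08 on the first scan day, 0.17 against sham 3 and 0.03 without orchidectomized 3. Choroid plexus genes had 0.21, with 22 of 28 higher (adjusted p 1.90e-05; adjusted p = 0.824 with an estimated correlation), including Ttr and Sostdc1 at 1.34. The choroid plexus median was -0.18 on the shared slide, -0.04 on the first scan day and 0.62 against sham 3. Oligodendrocyte and myelin genes had -0.27, with 20 of 23 lower (adjusted p 6.81e-05; adjusted p = 0.824 with an estimated correlation), and the claudin gene Cldn11 and the myelin glycoprotein gene Mog differed by -0.60 and -0.58. Their median was -0.59 on the shared slide, -0.39 on the first scan day, -0.14 against sham 3 and -0.18 without orchidectomized 3. On sham 1 the myelin list's mean log2 value was 1.29, where the orchidectomized arrays and sham 3 lay between 0.73 and 1.05. Markers of thalamus, striatum and hypothalamus were higher there too. Those of cortex were not, with -2.50 on sham 1 against -2.58 to -2.32. Neither were those of choroid plexus, with -3.34 against -3.98 to -3.10. Thalamus and habenula genes had a mean of -2.32 on sham 1 against -3.31 to -2.92 on those 4 arrays, striatum genes -1.99 against -2.75 to -2.55 and hypothalamus genes -3.74 against -4.33 to -4.18. The region markers were not the only lists raised on sham 1. Olfactory receptor genes had -6.22 there against -7.11 to -6.79, and taste receptor genes -6.41 against -7.81 to -7.22. Sham 1 also had the most probes well above background, 26176. The cause of these shifts was not tested. Blood cell genes had -0.45, with 13 of 17 lower (adjusted p 0.00605; adjusted p = 0.824 with an estimated correlation). Alas2, the erythroid heme synthesis enzyme gene, differed by -1.06, and the list's median was -1.14 on the shared slide, -0.51 on the first scan day, -0.11 against sham 3 and -0.23 without orchidectomized 3. The blood list's mean log2 value was -2.60 on sham 1 and -3.43 on sham 3, and -3.72 to -3.19 on the orchidectomized arrays.

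Glucocorticoid response genes had a median of -0.23, with 17 of 22 lower (adjusted p 0.0141; adjusted p = 0.824 with an estimated correlation). Klf9 differed by -0.28 and the metallothionein gene Mt1 by -0.48, and the list's median was -0.17 on the shared slide, -0.04 on the first scan day and -0.43 against sham 3. Olfactory receptor genes had -0.12, with 254 of 351 lower (adjusted p 0.00053; adjusted p = 0.824 with an estimated correlation), and this turned to 0.19 with normexp and 0.06 with quantile normalization. Genes bright on both remaining sham arrays alone could enter this list, which favours lower values. Over 6 arrays 296 of its genes were tested, with 145 higher and 151 lower. Astrocyte genes had 0.15 (adjusted p 0.00053), microglial genes 0.08 (adjusted p 0.0145), heat shock genes 0.12 (adjusted p 0.0145) and antigen presentation genes 0.09 (adjusted p 0.0139). Taste receptor genes had -0.29 (adjusted p 0.0229), and thalamus and habenula genes -0.24 (adjusted p 0.0316). With an estimated correlation the adjusted p of these lists was 0.824, and 0.832 for antigen presentation. On the first scan day the medians were 0.04 for astrocytes, -0.10 for microglia, 0.07 for heat shock, -0.03 for antigen presentation, -0.64 for taste receptors, -0.34 for thalamus and habenula and -0.20 for olfactory receptors. Against sham 3 they were 0.25, 0.26, 0.09, 0.26, -0.06, 0.01 and -0.02 in the same order. With scan day as a block the calls of the ribosomal protein, choroid plexus, astrocyte, microglial, antigen presentation and glucocorticoid response lists ended. Leaving out orchidectomized 3 ended those of the blood cell, glucocorticoid response, antigen presentation and thalamus and habenula lists, with medians of -0.23, -0.21, 0.01 and -0.14. Leaving out orchidectomized 2 ended those of the olfactory receptor, taste receptor, thalamus and habenula, heat shock, microglial and antigen presentation lists, with medians of -0.07, -0.20, -0.34, 0.07, 0.04 and 0.07. Leaving out orchidectomized 1 ended those of the glucocorticoid response, heat shock, taste receptor and thalamus and habenula lists, with medians of -0.23, 0.09, -0.30 and -0.34. Leaving out sham 1 ended those of the myelin, blood cell, heat shock, taste receptor and thalamus and habenula lists. Without sham 3 those of the choroid plexus, astrocyte, microglial, antigen presentation and glucocorticoid response lists ended. Over all lists 0 genes were called over all genes tested and 3 adjusted over the list alone, namely Ttr in the amyloid and tau list and Olr655 and Or4c107 among the olfactory receptors.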

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

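The alternatives to the comparison without the array labelled sham 2 were chosen after seeing the data. The count of probes called over 6 arrays was 0 and stayed 0 in 16 of 19 alternatives. It was 1 with quantile normalization, 13 with array weights, which gave the array labelled sham 2 a weight of 0.028, and 1 with the choroid plexus covariate. With the replicate block the count was 0 and 25 lists were called. Deviations from the group mean of arrays with the same number correlated at 0.03, -0.02 and -0.02. The sham mean includes the array labelled sham 2, whose profile dominates all sham deviations. These values therefore cannot tell whether the numbers pair the arrays. The 25 lists became 10 with array weights, 7 with slide and 9 with scan day as a block, and 0 with an estimated correlation. Leaving out each array gave 13 to 25 lists, with 13 without sham replicate 2. Of the 9 named genes, 0 kept their direction with an unadjusted p under 0.01 with normexp, 4 with quantile normalization, 3 with the strict brightness filter, under which only these 3 were tested, 5 with the replicate block and 2 with scan day as a block. Leaving out each array kept 4 to 9 of them.

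Without the array labelled sham 2 the count of probes was 2 with quantile normalization, 1 with median scaling, 18 with the authors' deposited values and 10 with scan day as a block. Leaving out a further array gave 0 to 251, with 22 without sham 1 and 251 without sham 3, each leaving a lone sham array that was assumed to vary like the others. The 13 lists became 7 with quantile normalization, 8 with the choroid plexus covariate and 0 with an estimated correlation, and leaving out a further array gave 8 to 13. The cause of these changes was not tested. Where arrays were left out, fewer arrays entered and the brightness filter asked for fewer arrays.

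Directions turned as follows, as medians of log2 differences. With array weights they were -0.05 for neurogenesis, -0.08 for antigen presentation, -0.26 for myelin, -0.02 for choroid plexus and -0.07 for striatum. With slide as a block they were -0.09 for synaptic plasticity, 0.09 for antigen presentation, -0.09 for glutamatergic neurons, -0.17 for microglia, -0.59 for myelin, -0.03 for oligodendrocyte precursors, -0.20 for dentate gyrus, -0.12 for CA1 and subiculum, -0.14 for CA2 and CA3 and -0.23 for striatum. With scan day as a block they were -0.03 for neurogenesis, -0.03 for antigen presentation, -0.39 for myelin, -0.04 for choroid plexus and -0.12 for striatum. With the choroid plexus covariate they were 0.04 for antigen presentation and -0.08 for myelin. Without the array labelled sham 2 they were -0.10 for neuropeptides, 0.09 for antigen presentation, -0.09 for glutamatergic neurons, -0.02 for GABAergic interneurons, -0.27 for myelin, -0.09 for oligodendrocyte precursors, 0.21 for choroid plexus, -0.02 for meninges, -0.14 for dentate gyrus, -0.04 for CA1 and subiculum and -0.07 for striatum. Over leaving out each array, the other end of the range was 2.45 for neuropeptides, -1.42 for antigen presentation, 3.59 for glutamatergic neurons, 2.48 for GABAergic interneurons, 1.73 for myelin, 2.30 for oligodendrocyte precursors, -3.82 for choroid plexus, -1.14 for meninges, 1.88 for dentate gyrus, 1.55 for CA1 and subiculum and 1.12 for striatum. A turn is one of the camera test's direction, so a median near 0 can keep its sign. In the comparison without the array labelled sham 2, normexp gave 0.19 for olfactory and 0.19 for taste receptors, and quantile normalization 0.06 for olfactory receptors. Scan day as a block gave -0.04 for glucocorticoid response and -0.10 for microglia. Leaving out sham replicate 1 as well gave 0.01 for thalamus and habenula and -0.06 for taste receptors, and sham replicate 3 as well -0.04 for glucocorticoid response. Normexp gave all tested probes a median of 0.069 over 6 arrays and 0.077 without the array labelled sham 2. It turned Lrrc71 to 0.09 and Or1e27 to 0.11, and without that array Or4c107 to 0.09, Or1n1b to 0.01 and Olr1493 to 0.08. Most of these genes lay near background, where signal over background limits the values.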

Other observations

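The tests of the array labelled sham 2 and of the choroid plexus trace were chosen only after the result was seen, and the other tests before. The criterion of the trace test was also changed after its result: as first set it counted against a trace, and the relation to the excess on that array was then added because a hippocampal baseline can hide a small share. Its split by sham array was added last.

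The array labelled sham 2 stood apart from the other 5 arrays. A choroid plexus admixture of at most 50% of the RNA would leave glutamatergic genes at most 1 log2 unit lower, and their median was -6.60 (SD over genes 2.28). An exchange of labels with a hippocampal sample of the orchidectomized group would not by itself give this profile. Glutamatergic neuron means were 1.32 to 1.41 on the other 5 arrays and -4.77 on this one. Whether labels were exchanged as well was not excluded. The lowest best correlation of an orchidectomized array with another array besides the array labelled sham 2 was 0.990. An ordinary hippocampal partner would give that too. RNA of another tissue rich in choroid plexus, through a wrong label or an exchange with an outside sample, remains a candidate explanation, with the choroid plexus median at 7.70 (SD over genes 2.64). No biological explanation was tested for a profile seen in 1 animal of the sham group.

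NM_001037357 was well above background on every sham array and on no orchidectomized array. With scan day as a block the probe with the smaller p had -4.98 with a standard error of 0.29, which rests on sham 1 as the lone sham array of that day and follows from how the transcript was picked, so the planned limit of 2 standard errors did not decide and scan day stays open. Differences between individual animals stay open as a possible explanation too. Without the array labelled sham 2, 29 probes were well above background on all arrays of one side and on none of the other with a gap over 2 log2 units, and the highest count among the other splits of the 5 arrays was 48; 3 of the 10 splits gave as many as the real one. An effect of the surgery is also open, and splits this few cannot give a share under 0.05.

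Ttr was higher in the orchidectomized arrays when the array labelled sham 2 was left out, and a larger trace of choroid plexus in those dissections may account for it. The other 22 choroid plexus genes well above background on all 5 other arrays and at least 5 log2 units higher on the array labelled sham 2 had a median difference of 0.21 (SD 0.44), with 18 higher, below the 1.58 of Ttr, itself a lower bound because of saturation. Across those genes the difference grew with the excess on the array labelled sham 2 (Spearman's rho 0.582, across genes, which are not independent replicates), as a hippocampal baseline of some genes would give, so a small share cannot be told apart from none. Against sham 1 alone on the first scan day the 22 genes had a median of -0.07 (SD 0.58, rho 0.0785). As a set they thus showed no larger trace than sham 1 itself may carry, and a small one could be missed. Ttr differed by 1.34 there (standard error 0.36 with scan day as a block). Against sham 3 alone Ttr differed by 1.82 and the genes by 0.62 (SD 0.62, rho 0.691). The sign of Ttr was fixed in both comparisons by the rule of groups without overlap. Each comparison rests on 1 sham array, which leaves both the trace and scan day open. An effect of the surgery on Ttr stays open and untested.

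The 3 against 3 arrays allow 10 splits, too few for a share under 0.05. The real split gave 0 probes and the highest other 0, so all 10 gave as many. It gave 25 lists and the other splits 18 to 23, so 1 gave as many. The count of lists was thus large under any grouping of these arrays, with the array labelled sham 2 on one side of each.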
